A study of Rattus norvegicus with 11 samples.

How the data were processed

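Messenger RNA was profiled in soleus muscle from 11 male rat offspring, 6 of control mothers and 5 of high-fat mothers. Per the labels' protocols, poly(A) RNA was enriched from 2 µg of total RNA per animal and sequenced for 36 cycles on an Illumina Genome Analyzer. The labels give the mothers' diets in 2 places that differ slightly, as 6% against 23.3% fat in one and 7% against 23.5% in the other, with 10% and 20% sucrose in both. The authors deposited 1 table of raw read counts per gene symbol, with 16810 rows and 1 column per animal. Per the submitters' processing notes the tools were FastQC, BWA, HTSeq and edgeR, without versions, and the genome build and annotation are not given in the sources used here. Gene positions are therefore not given. Reads of 36 cycles are short, so counts of closely related genes, such as Hspa1a and Hspa1b or ribosomal protein genes with many pseudogenes, can be split or lost between copies. How the counting treated strand is not given in the sources used here.

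Columns were matched to animals by the animal names in the labels, and groups came from the diet label. The high-fat numbers in the deposited column names differ in part from those used here. High-fat animals 1 to 5 here are the animals named C91, H1, C25, H20 and A37. Each animal came from a litter of its own and served as the replicate. The labels also give body, fat depot and organ weights, plasma insulin, glucose and HOMA-IR for each animal, of which high-fat animal 5 lacks the last 3. HOMA-IR in the labels equals insulin in mU/L times glucose divided by 22.5. Of the row names, 14002 equal a current symbol in the RefSeq table of assembly GRCr8, 2346 match an older symbol and 462 match neither. A total of 24 rows carry names turned into dates by spreadsheet software and hold 0.107% of counts. They stayed in the fit and are not named.

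Count totals per library ran from 10.2 to 15.4 M (M, mega). A gene with 0 counts in a library may have had up to 3, which is 0.195 to 0.295 counts per M counts (CPM), and such limits cover counting error only. Genes were kept by edgeR's filterByExpr with the group, which left 10814 and removed 5996, 2712 of these with no count in any library. Libraries were scaled by the trimmed mean of M values (TMM; factors 0.897 to 1.12). The main test was edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.234. Standard errors are the log2 fold change divided by the square root of F. CPM values are TMM-scaled.

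Gene groups were 35 lists of textbook members fixed before the data were examined, as were the design, the rule for named genes and the main alternatives. The 34 lists with at least 3 measured members were tested with limma's camera on log2 CPM (prior count 2) with its preset correlation of 0.01, then with an estimated correlation and with fry. A list of 13 mitochondrially encoded subunits had no row under the listed symbols and is not analysed here. List medians are over edgeR log2 fold changes unless a linear fit on log2 CPM is named. A list score is the mean over members of log2 CPM minus the member's mean over libraries. Counts of called members are given over all genes and adjusted over the list alone.

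Named genes were, per direction, the 12 with the smallest p among those passing or, where fewer than 12 passed, enough to fill up to 6, then up to 4 members per list by p, and always Ppargc1a, Irs1, Pik3r1, Slc2a4, Myh7, Myh2, Il6 and Adipoq. Groups of fewer than 5 counted genes were named in full. Some genes that this rule picks are not reported here, though they stayed in the fit and the lists.

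Animal measures were compared by two-sided exact permutation tests of the difference in means over all 462 splits (210 where 1 animal had no value), with adjustment over 13 measures. Correlations used 100000 random pairings with 10 or more animals and all pairings with fewer.

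Alternatives for the gene test were RLE, upper quartile or library size scaling, no filter or a stricter one, DESeq2, edgeR's likelihood ratio, exact and robust tests, limma voom with and without quality weights, the first letter of the animal's name as a covariate, and leaving out each library in turn. Similar alternatives were run for the lists, measures and correlations. Results of the gene and list tests were also counted over 100 splits of the 11 libraries into 6 and 5, the real one included.

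The gene test was tested on simulated data made from the real means, library sizes and dispersions for the maternal high-fat against control comparison. Of 200 changed genes among 10727 in the fit, 34.3% were recovered at 1.5-fold, 65.7% at 2-fold and 97.0% at 4-fold, with 9 unchanged genes among 140 called. A list raised 1.5-fold was called and no other list was. The simulation held genes independent of each other.

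Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.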

Results

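Skeletal muscle RNA was measured in 11 male Sprague Dawley rats aged 12 months, each from a litter of its own. The mothers of 5 animals had eaten a diet high in fat and sugar for 3 weeks before mating and through pregnancy and lactation (the high-fat group). The mothers of the other 6 had eaten control chow. All offspring were weaned at day 21 and then kept on standard chow, so the groups differed by the mother's diet and not by their own adult diet. The muscle was the soleus, a postural hind limb muscle built mainly of slow, oxidative fibres. Each library held 10.2 to 15.4 M counted reads (M, mega), with a mean of 12.7 ± 1.83 M in the control group (SD, n = 6) and 12.9 ± 2.24 M in the high-fat group (SD, n = 5), a difference within the spread between animals (two-sided exact permutation test, p = 0.864). Between 12333 and 12886 genes had at least 1 count per library. Libraries of one group differed by at least 25.0 times the sampling noise in each of 25 pairs, so none was counted as a repeat of another.

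The first comparison asked whether offspring of high-fat mothers differed in body composition and insulin sensitivity, the subject of the series title. Plasma insulin was 2.27 ± 0.493 ng/ml in the high-fat group (SD, n = 4) and 1.61 ± 0.252 ng/ml in the control group (SD, n = 6), 1.41 times as high. HOMA-IR, an index of insulin resistance formed from insulin and glucose, was 18.9 ± 9.35 against 11.3 ± 2.29. Abdominal fat weighed 15.1 ± 1.80 g (SD, n = 5) against 11.5 ± 3.06 g (SD, n = 6) and lay above the control mean in 5 of 5 high-fat animals. Insulin and HOMA-IR lay above the control mean in 3 of the 4 high-fat animals measured. Body weight was 750 ± 138 g against 773 ± 94.2 g, and total fat was 9.41 ± 4.42% of body weight against 6.02 ± 1.70%. In two-sided exact permutation tests the differences gave p = 0.0238 for insulin, p = 0.0333 for HOMA-IR, p = 0.0498 for abdominal fat, p = 0.0974 for fat as a share of body weight and p = 0.740 for body weight. Over the 13 measures tested, none passed after Benjamini-Hochberg adjustment, with 0.216 as the smallest adjusted value. With only 210 splits for insulin, glucose and HOMA-IR, none of these could have passed that adjustment alone. Perirenal fat (45.2 ± 27.9 against 27.2 ± 14.1 g), mesenteric fat (9.83 ± 2.71 against 9.02 ± 2.44 g) and total fat (70.1 ± 29.9 against 47.7 ± 18.5 g) also overlapped between groups. So did glucose (7.35 ± 2.48 against 6.35 ± 0.924 mmol) and the weights of the heart, liver, pancreas and brain. High-fat animal 4 had the highest HOMA-IR, 32.1, and without it the HOMA-IR difference was 3.19 in place of 7.59 (exact permutation p = 0.155) and the glucose difference was -0.21 mmol in place of 1 mmol. In the labels 3 of the 6 control animals have the same glucose value of 6.36 mmol. Whether it was measured in each of them is not given, so glucose, HOMA-IR and their relations carry that doubt and insulin does not. The mesenteric fat difference of 0.816 g ran from 0.0691 to 1.93 g without 1 animal. Without high-fat animal 1 the difference in total fat was 1.67% of body weight in place of 3.39% (exact permutation p = 0.243) and that in perirenal fat 10.5 g in place of 18.0 g. Without high-fat animal 5 these were 4.61% (exact permutation p = 0.0143) and 27.3 g (exact permutation p = 0.0476). Without high-fat animal 5 the total fat difference was 32.9 g (exact permutation p = 0.0429). Of all measures, 5 then had p under 0.05 before adjustment and none after it (smallest adjusted value 0.124).

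**Figure D1:**
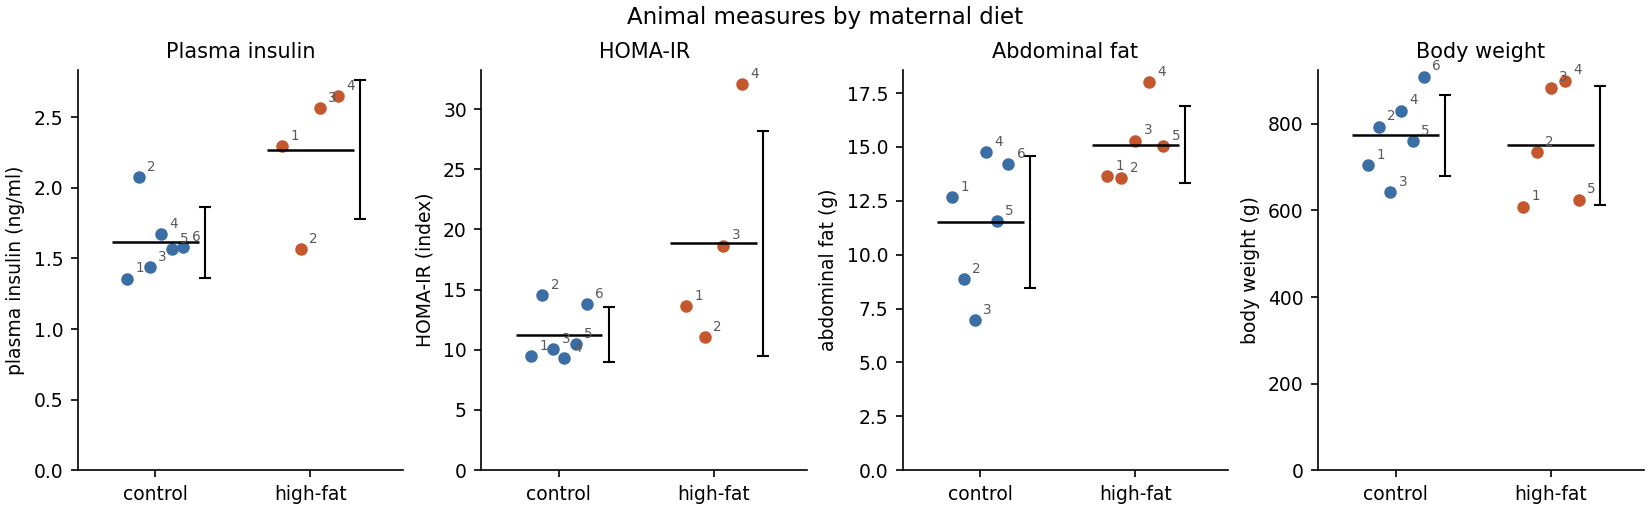
Plasma insulin (ng/ml), HOMA-IR (index), abdominal fat (g) and body weight (g) per animal, numbered by replicate within the control (blue) and high-fat (orange) groups; horizontal lines are group means and error bars are 1 SD. Insulin lay above every control animal in 3 of the 4 high-fat animals measured, and body weights overlapped.

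The second comparison asked which muscle transcripts differed with the mother's diet. Among the genes furthest apart, Gadd45a, a stress-inducible growth arrest gene, stood at 93.7 ± 45.0 normalised counts per M reads (CPM) in the high-fat group (SD, n = 5) and 31.95 ± 8.84 CPM in the control group (SD, n = 6), a log2 fold change of 1.55 ± 0.31 (SE). P4ha1, a catalytic subunit of the prolyl 4-hydroxylase that modifies collagen, stood at 37.4 ± 3.23 against 26.7 ± 2.57 CPM (log2 fold change 0.48 ± 0.09). The flavin monooxygenase genes Fmo1 (0.54 ± 0.11) and Fmo2 (0.78 ± 0.17), the transcription factor gene Atoh8 (1.23 ± 0.25) and the cell adhesion receptor gene PVR (0.77 ± 0.16) completed the 6 genes with the smallest p on the higher side. On the lower side, the LIM domain gene Fhl3 stood at 120 ± 12.7 against 185 ± 25.4 CPM (log2 fold change -0.62 ± 0.11) and Mfsd6l at 2.23 ± 0.643 against 5.14 ± 0.986 CPM (-1.22 ± 0.22). Tox2 (-1.61 ± 0.42), Mk1 (-0.34 ± 0.10), Trim35 (-0.33 ± 0.10) and Cbx8 (-0.61 ± 0.18) were next.

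None of these passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 10814 genes tested, 0 were called higher and 0 lower, and the smallest adjusted p was 0.471. At an unadjusted p under 0.05 there were 523 genes, 373 higher and 150 lower, where chance alone would give 540.7. In 40 genes the groups did not overlap at all (0.370% of those tested), and chance gives 0.433%. Other tools were less strict. DESeq2 called 7 genes, edgeR's likelihood ratio test 8 and its exact test 8, while limma voom called 0 with or without quality weights. All of DESeq2, the likelihood ratio test and the exact test called Atoh8, Fhl3, Fmo1, Gadd45a, Mfsd6l and PVR. P4ha1 was called by DESeq2 alone, and Fmo2 and Klk1c7 by the likelihood ratio and exact tests. Klk1c7, one of a family of closely related kallikrein genes among which short reads are hard to place, had a log2 fold change of 3.21 ± 0.77 in the quasi-likelihood fit and was named after its values were seen. It stood at 28.8 and 39.5 CPM in high-fat animals 1 and 5 and at 9.30 CPM in animal 3. High-fat animals 2 and 4 had 0.640 and 3.95 CPM, against 0.533 to 3.35 CPM in the control group.

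**Figure D2:**
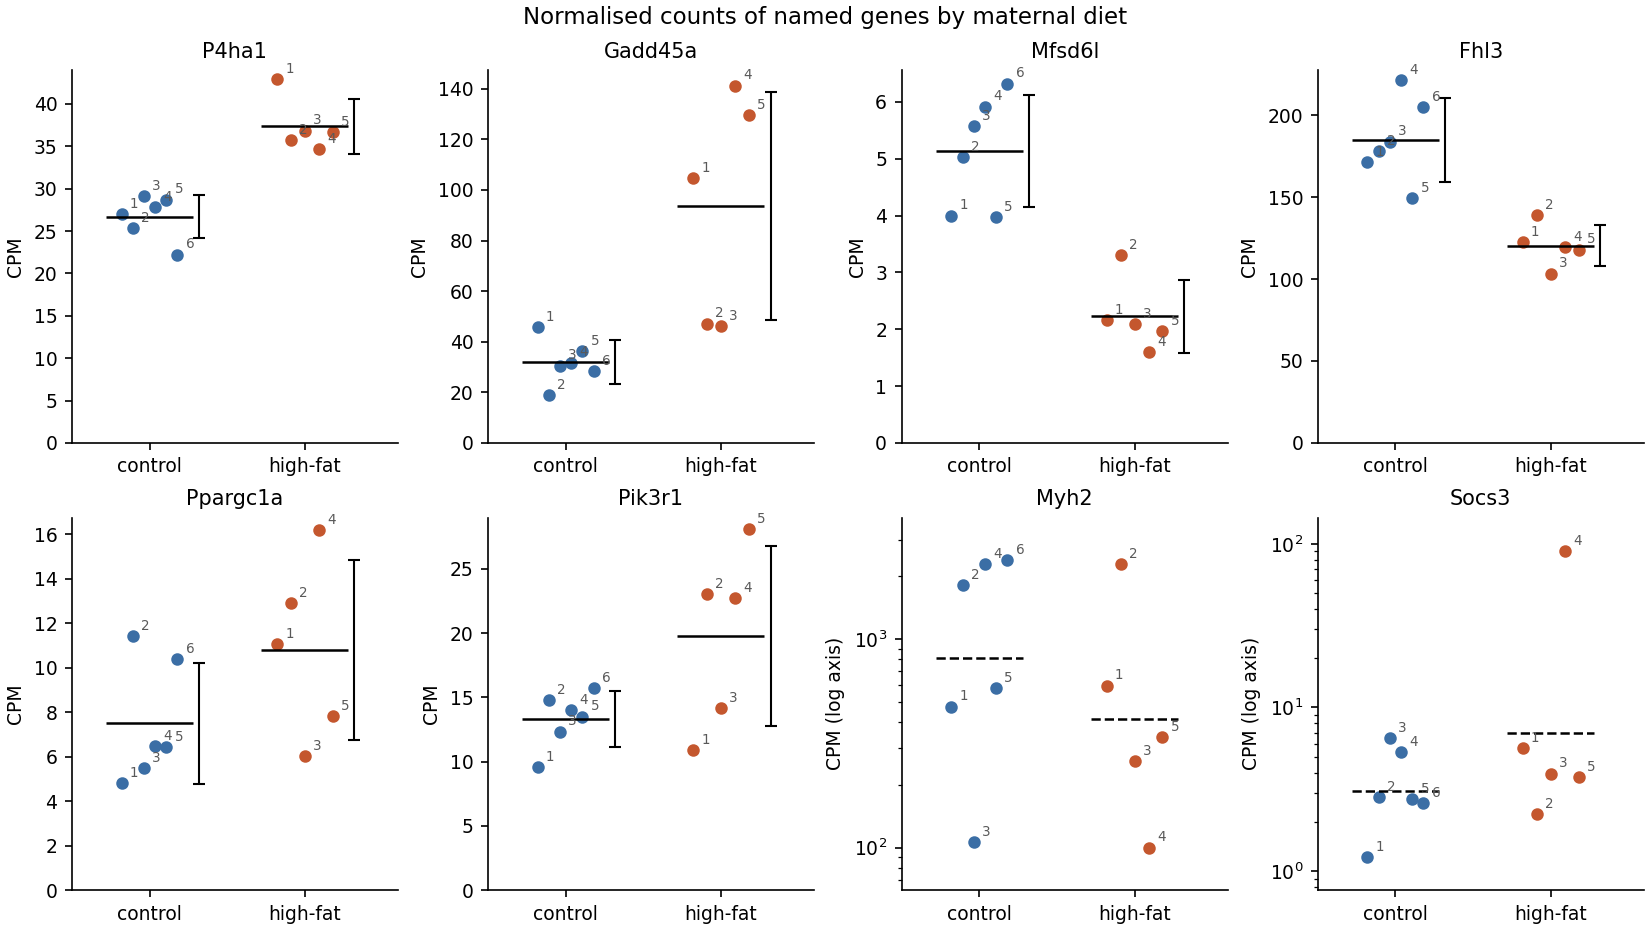
Normalised counts (CPM) of 8 named genes per animal, numbered by replicate within the control (blue) and high-fat (orange) groups; solid lines are means with error bars of 1 SD, and for Myh2 and Socs3, on log axes, dashed lines are geometric means. P4ha1, Gadd45a, Mfsd6l and Fhl3 did not overlap between groups, and Socs3 in the high-fat group was set by animal 4 at 90.4 CPM.

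Genes of insulin action were examined because of the study's subject. Pik3r1, a regulatory subunit of phosphoinositide kinase, had a log2 fold change of 0.57 ± 0.22 (19.8 ± 7.04 against 13.3 ± 2.17 CPM), while Irs1 (-0.07 ± 0.32) and the glucose transporter gene Slc2a4 (-0.12 ± 0.17, and -0.21 to -0.02 without 1 library) differed by less than their errors with all animals. The coactivator gene Ppargc1a, which drives mitochondrial biogenesis, had 0.52 ± 0.28 (10.8 ± 4.04 against 7.51 ± 2.73 CPM). All had edgeR adjusted p of at least 0.974. Of 33 measured insulin signalling and glucose uptake genes, 19 were higher and 14 lower, with a median log2 fold change of 0.06 and an adjusted p of 0.138 in limma's camera test. Foxo1, a transcription factor restrained by insulin signalling, had a log2 fold change of 0.60 ± 0.25. Without high-fat animal 4 the log2 fold changes of Foxo1 and Ppargc1a were both 0.32. No member was called over all genes or adjusted over the list alone. Camera with its preset correlation called the list higher without control animal 3 (linear-fit median 0.10, adjusted p = 0.0106). With all animals and an estimated correlation camera gave the list an adjusted p of 0.865.

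The third comparison concerned gene groups, led by oxidative phosphorylation (OXPHOS), which the series title names. Of 74 measured nuclear OXPHOS genes, 71 had a lower mean and 3 a higher mean in the high-fat group, by a median log2 fold change of only -0.12. Complex I member Ndufa2 (-0.23 ± 0.15) and complex IV member Cox7b (-0.36 ± 0.19) were among those with the smallest p (-0.14 and -0.18 without control animal 4), and no member was called over all genes or adjusted over the list alone. Camera with its preset correlation of 0.01 called the list lower (adjusted p = 5.48e-05), as it did complex I alone (median -0.12, adjusted p = 0.000981). With an estimated correlation the adjusted p was 0.865 for both, the estimate being 0.747 for the OXPHOS members. With all animals and the preset correlation it did not call complex II (-0.11, adjusted p = 0.261), complex III (-0.13, adjusted p = 0.0682), complex IV (-0.09, adjusted p = 0.179) or complex V (-0.12, adjusted p = 0.0618). With the first letter of the animal's name as a covariate it called complex III (linear-fit median -0.21, adjusted p = 0.0113), complex IV (-0.16, adjusted p = 0.0168) and complex V (-0.15, adjusted p = 0.00172). Each was also called without control animal 3 or high-fat animal 1. Complex III was further called without control animal 1 or high-fat animal 2, and complex V without control animal 1, 2 or 5 or high-fat animal 2. These calls rest on the preset correlation, with which 63 of 100 splits of the libraries, the real one included, called at least 10 lists. The mean OXPHOS score was 0.05 ± 0.28 in the control group and -0.06 ± 0.23 in the high-fat group on the log2 scale, a difference within the spread between animals (two-sided exact permutation test, p = 0.537; adjusted over 34 lists, 0.863). The preset call was lost without control animal 4 (linear-fit median -0.04), control animal 6 (-0.04) or high-fat animal 5 (-0.01), against -0.11 with all animals, and so was that of complex I. Across the 11 libraries the OXPHOS score was lower where a composition score, the mean of the macrophage, matrix and adipocyte scores chosen after the data were seen, was higher (Pearson's r = -0.85, permutation p = 0.00047; Spearman's rho = -0.86, permutation p = 0.00132; adjusted over 6 relations, 0.00094 and 0.00396; r = -0.72 without the 2 libraries farthest from the median). With the composition score as a covariate camera called neither the OXPHOS list (linear-fit median -0.012, adjusted p = 0.645) nor complex I.

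Of the other metabolic and fibre lists, camera with the preset correlation called 4, all lower. The mitochondrial ribosome list had 63 of 70 members lower (median -0.10, adjusted p = 3.83e-06, or 0.865 with an estimated correlation), with Mrps2 at -0.29 ± 0.11 and Mrps27 at -0.32 ± 0.14. Glycolysis and glycogen genes had 18 of 19 lower (-0.14, adjusted p = 0.00967, or 0.865 with an estimated correlation), among them Ldha at -0.32 ± 0.19 and Pkm at -0.22 ± 0.13. The TCA cycle had 14 of 17 lower (-0.11, adjusted p = 0.0439, or 0.865 with an estimated correlation), among them Idh2 at -0.21 ± 0.13. Fast fibre genes had 12 of 13 lower (-0.65, adjusted p = 0.0439, or 0.865 with an estimated correlation), with the myosin heavy chain genes Myh2 at -0.83 ± 0.81, Myh1 at -1.19 ± 0.65 and Myh4 at -1.63 ± 0.76. Myh2 ranged from 107 to 2391 CPM among control animals and from 100.1 to 2282 CPM among high-fat animals. Without control animal 2 Myh4 was -0.12, without control animal 5 Myh1 was -0.19, and Myh2 was -0.55 without high-fat animal 4 and -1.97 without high-fat animal 2. With the composition score as a covariate, chosen after the data were seen, all 4 calls ended. The linear-fit medians were then -0.04 for the mitochondrial ribosome (adjusted p = 0.0678), -0.04 for glycolysis (0.347), -0.04 for the TCA cycle (0.347) and -0.11 for fast fibres (0.510). Without high-fat animal 5 all 4 preset calls were lost, with linear-fit medians of -0.04 for the mitochondrial ribosome, -0.04 for glycolysis, -0.03 for the TCA cycle and -0.51 for fast fibres, against -0.09, -0.13, -0.09 and -0.46 with all animals. Over all fits without 1 library these medians ran from -0.14 to -0.04, -0.20 to -0.04, -0.15 to -0.03 and -0.84 to -0.22 in the same order. The glycolysis call was also lost without control animal 6, high-fat animal 1 or 3, the TCA call without control animal 1, 5 or 6 or high-fat animal 1 or 3, and the fast fibre call without control animal 2, 4, 5 or 6 or high-fat animal 3 or 4. RLE scaling, upper quartile scaling and the name letter as a covariate each ended the fast fibre call as well. Slow fibre genes (median -0.06, adjusted p = 0.234), fatty acid oxidation (-0.07, adjusted p = 0.179) and lipid uptake, storage and synthesis (0.05, adjusted p = 0.719) were not called with all animals. Slow fibre genes were called without control animal 2 or high-fat animal 1 and with the name letter as a covariate, and fatty acid oxidation without control animal 3 or high-fat animal 1. The slow myosin gene Myh7 was level with all animals (-0.02 ± 0.16). Mitochondrial biogenesis and dynamics (adjusted p = 0.522) and antioxidant and uncoupling genes (adjusted p = 0.537) each had a median of -0.04, a linear-fit mean of 0.01 and a test pointing lower.

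On the higher side camera called 4 lists. Inflammatory signalling genes were higher in 21 of 24 (median 0.45, adjusted p = 5.48e-05, or 0.865 with an estimated correlation), with Il6r at 0.76 ± 0.23, Stat3 at 0.30 ± 0.11, Myd88 at 0.63 ± 0.23 and Socs3, a feedback inhibitor of cytokine signalling, at 2.61 ± 0.90. Socs3 was 90.4 CPM in high-fat animal 4 and 1.22 to 6.48 CPM in all other animals, and without that animal its log2 fold change was 0.16, that of Il6r 0.49 and that of Myd88 0.30. Macrophage markers were higher in 17 of 17 (0.67, adjusted p = 0.000981, or 0.865 with an estimated correlation), led by the scavenger receptor gene Cd163 at 1.31 ± 0.45 (57.6 ± 41.5 against 23.3 ± 7.66 CPM) and the mannose receptor gene Mrc1 at 0.90 ± 0.41. Extracellular matrix and fibroblast genes were higher in 18 of 22 (0.28, adjusted p = 0.0134, or 0.865 with an estimated correlation), including the matrix cross-linking enzyme gene Lox at 1.12 ± 0.44 (0.69 without high-fat animal 5) and Timp1 at 0.81 ± 0.30. Satellite cell, regeneration and denervation genes were higher in 15 of 16 (0.33, adjusted p = 4.93e-05, or 0.865 with an estimated correlation). In that list Gadd45a and the acetylcholine receptor gene Chrna1 (1.19 ± 0.33, 83.1 ± 47.2 against 36.5 ± 9.30 CPM) were called adjusted over the list alone (adjusted p = 0.00336 and 0.0257), and neither over all genes. Over the 34 lists 4 members were called in this way, Gadd45a, Chrna1, S100a8 and Nr4a3. Such calls are not adjusted for the number of lists. Fry called 0 of the 34 lists. Without high-fat animal 5 the macrophage and matrix calls were lost (linear-fit medians 0.18 and 0.16, against 0.48 and 0.31 with all animals, and up to 0.82 for macrophage markers without high-fat animal 2), and the matrix call was also lost without control animal 6 (0.13), high-fat animal 3 (0.18) or high-fat animal 4 (0.20). The matrix call was lost with the name letter as a covariate too. Without high-fat animals 4 and 5 together, a pair chosen after the data were seen, the macrophage and matrix medians turned negative. The inflammatory call was also lost without that pair.

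**Figure D3:**
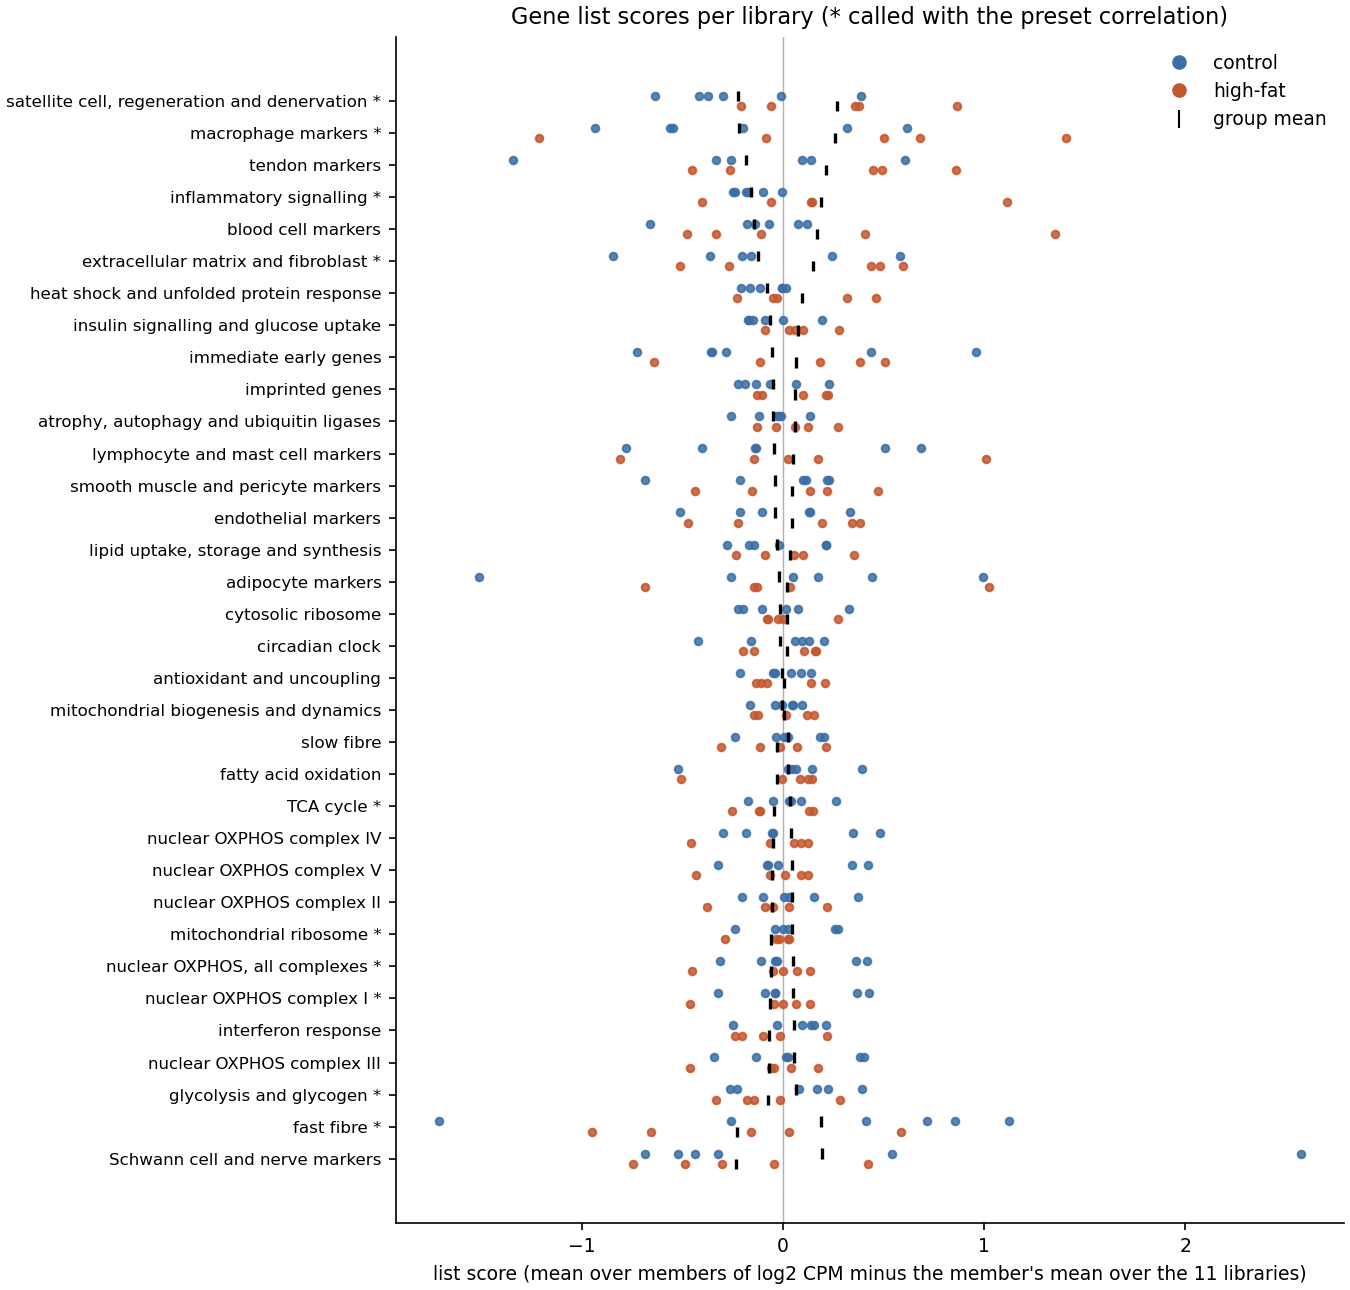
Score of each of the 34 gene lists per library (mean over members of log2 CPM minus the member's mean over the 11 libraries), for control (blue) and high-fat (orange) animals; black ticks are group means and asterisks mark the 10 lists called with the preset correlation. The groups overlap in every list, including OXPHOS with group means of 0.05 and -0.06.

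Beyond the macrophage, matrix, satellite cell and fibre lists above, markers of the remaining cell types and tissues were not called with all animals. Their medians were 0.42 for tendon (adjusted p = 0.138), 0.12 for endothelium (0.511), 0.08 for smooth muscle and pericytes (0.511), 0.09 for lymphocytes and mast cells (0.739) and 0.02 for adipocytes (0.739), with the adipokine gene Adipoq at -0.16 ± 0.60. Schwann cell and nerve markers had a median of -0.80 with 9 of 9 lower (adjusted p = 0.109). Control animal 5 stood apart in them, with the myelin gene Mbp at 844 CPM against at most 96.8 CPM in the others. Without that animal the log2 fold change of Mbp went from -2.28 to -0.17 and that of Prx, a further myelin gene, from -1.38 to 0.19. Blood cell markers had a median of 0.03, or -0.04 in the linear fit on log2 CPM, with means of 0.60 and 0.31 and a test pointing higher (adjusted p = 0.675). Their member S100a8, a neutrophil gene, was called adjusted over the list alone (2.28 ± 0.69, adjusted p = 0.0388), with a log2 fold change of 1.39 without high-fat animal 4. Immediate early genes had a median of 0.01, or -0.06 in the linear fit, and a mean of 0.12 (adjusted p = 0.584), with Nr4a3 called adjusted over the list alone (2.45 ± 0.66, adjusted p = 0.0428) and a log2 fold change of 1.63 without high-fat animal 1. Heat shock and unfolded protein response genes had 0.15 (adjusted p = 0.0682), atrophy and autophagy genes 0.03 (0.384), the cytosolic ribosome 0.03 (0.371), interferon response -0.03 (0.554), the circadian clock 0.07 (0.923) and imprinted genes 0.06 (0.374). The clock list joins genes that ran opposite to each other, such as Arntl and Dbp (Pearson's r = -0.909). Camera's test of a common direction therefore cannot tell whether the clock differed. Without 1 library, camera called endothelium higher when high-fat animal 5 was left out (linear-fit median 0.25, adjusted p = 0.0136), and tendon without control animal 3 (0.47, adjusted p = 0.0198) or high-fat animal 1 (0.59, adjusted p = 0.0431). Heat shock genes were called higher without control animal 5 (0.14, adjusted p = 0.0298) or high-fat animal 5 (0.19, adjusted p = 0.00203). It also called nerve markers lower without control animal 1 (-0.51, adjusted p = 0.0289), immediate early genes higher without control animal 2 (0.17, adjusted p = 0.0490) and the cytosolic ribosome higher without control animal 4 (0.10, adjusted p = 0.000649). All these fits used the preset correlation. With it, 63 of 100 splits, the real one included, called at least 10 lists, so such calls alone decide little. Il6 had 0 to 3 counts in 10 libraries and 231 in high-fat animal 4, and was below the expression filter.

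The last comparison set the mean OXPHOS expression of each animal against its insulin resistance and size. Across the 10 animals with insulin values, it did not follow HOMA-IR (Pearson's r = -0.12, permutation test p = 0.6999; Spearman's rho = -0.01, permutation p = 1). It did not follow plasma insulin (r = -0.04, permutation p = 0.911; rho = 0.31, permutation p = 0.387) or glucose (r = -0.13, permutation p = 0.686; rho = -0.14, permutation p = 0.705) either. Across all 11 animals the relation with body weight was r = 0.59 (permutation p = 0.0552; rho = 0.45, permutation p = 0.165), and that with fat as a share of body weight was r = 0.39 (permutation p = 0.241; rho = 0.57, permutation p = 0.0719). None of the 5 relations passed after Benjamini-Hochberg adjustment (adjusted p of Pearson's r = 0.875, 0.911, 0.875, 0.276 and 0.603 in that order). Without the 2 animals farthest from the median, r was 0.17 for HOMA-IR, 0.16 for insulin, -0.68 for glucose (rho = -0.22) and 0.64 for body weight. For the fat share r was then 0.75 (exact permutation p = 0.0191, adjusted p = 0.0956). With group means subtracted, r was 0.59 for body weight and 0.59 for the fat share (adjusted permutation p = 0.151 for each). In control animals only, r was 0.91 for body weight (exact permutation p = 0.0194; rho = 0.94) and 0.88 for the fat share (exact permutation p = 0.0333; rho = 0.71), with an adjusted p of 0.0833 for both. Without 1 animal it ran from 0.47 to 0.72 for body weight, the highest without high-fat animal 1 (permutation p = 0.0186, adjusted p = 0.0932), and from 0.28 to 0.55 for the fat share.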

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

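Of the tests of explanations below, those on other splits of the libraries, composition, blood, the left-out library and the count of liver genes were written down after the result was seen, and those on library depth and the rank correlation of liver genes before. In 238 groups of values, 1 animal stood apart from its group 14 times, and chance alone gives about 11.9.

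High-fat animal 4 stood apart in single genes, which were not a list fixed beforehand and were not tested as a set. It held 231 counts of the cytokine gene Il6, against at most 3 in any other library, and Socs3 at 90.4 CPM, Dnajb1 at 166 CPM (33.3 to 40.4 CPM in the other high-fat animals) and Fmo2 at 64.2 CPM (34.3 to 40.2 CPM). Other genes high in that library were named after their values were seen: the endothelial adhesion gene Selp was 139 CPM against at most 6.30 CPM elsewhere, Icam1 108 CPM against at most 15.0 CPM, and the metallothionein gene Mt2A 45.4 CPM against at most 7.91 CPM. More blood in the sample was weighed as a source. The hemoglobin gene Hbb was highest in that library, at 619 CPM against 278 to 518 CPM in the others. It was raised by 0.60 on the log2 scale over the mean of the other 10 libraries, while the neutrophil genes S100a8 and S100a9 were raised by a median of 2.94. Some more blood may be present, but more whole blood alone argues poorly for these genes. The neutrophil genes were high in high-fat animal 1 as well, with S100a8 at 10.1 CPM and S100a9 at 17.4 CPM there, 20.1 and 28.9 CPM in high-fat animal 4, and at most 2.97 and 4.95 CPM elsewhere. That this 1 library makes the inflammatory list higher was tested by leaving it out. The linear-fit median went from 0.32 to 0.13, so the library set most of the size. The preset call held (adjusted p = 0.0281). That decides little, since 63 of 100 splits, the real one included, called at least 10 lists with the preset correlation. The call was lost without high-fat animals 4 and 5 together, and with an estimated correlation (adjusted p = 0.865). An acute illness or stress of that animal, and the mother's diet, remain open and untested.

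The OXPHOS list had its lower mean in the high-fat group partly through high-fat animal 5, which stood apart in its mitochondrial ribosome score (-0.29 against -0.03 to 0.03 in the other high-fat animals) and its fatty acid oxidation score (-0.50 against -0.01 to 0.15). Control animal 3 had scores of -0.24 and -0.52, so the lowest fatty acid oxidation score was in a control animal. Chance could not be excluded: 53 of 100 splits of the libraries, the real one included, gave an absolute OXPHOS median as large as 0.11, with 0.37 as the highest of the other splits. Log2 total counts as a covariate left the median at -0.10, but this test decides little, since it moved no list median by more than 0.0233. Depth itself was alike in the groups, with means of 12.7 M in control and 12.9 M in high-fat animals (exact permutation p = 0.864). That argues against library depth as the source of the group difference. The share of other cell types may account for it, though medians of their lists ran from -0.80 (nerve) to 0.67 (macrophage) and did not rise alike. With a composition score (mean of the macrophage, matrix and adipocyte scores) as a covariate the median went from -0.11 to -0.012 and the coefficient of the OXPHOS score from -0.107 ± 0.158 to -0.0041 ± 0.0930 (SE), so the call ended because the difference itself shrank, from a value already within its error. The macrophage and matrix lists in that score were themselves called higher in the high-fat group with the preset correlation. The shrinkage therefore cannot part a share of other cells from other effects of the mother's diet.

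In 3 libraries, counts of Alb, the albumin gene, a liver product, were 227 (control 1), 557 (high-fat 3) and 327 (high-fat 4), against at most 12 elsewhere. Traces of liver RNA in those libraries are a candidate source. The test written down first was a rank correlation of Alb with 20 liver genes not yet looked at. It did not pass (rho = 0.510, permutation p = 0.113), and Pearson's r was 0.392 (permutation p = 0.250). Without the 2 libraries farthest from the median of Alb, high-fat 3 and 4, rho was 0.393. These hold the 2 highest Alb counts, so a lower rho without them decides nothing. The test was to count against liver RNA at any p of 0.05 or more. The sum it uses is carried by Tf, Hpd and Rbp4, with means of 91.5, 22.5 and 12.2 CPM over all libraries, which can hide a small share. Over the 12 genes under 1 CPM, a limit that was not in the written test, Pearson's r was 0.962 (permutation p = 0.00073, adjusted over 6 relations 0.00109). That r is carried by the 3 libraries high in Alb. The rho of these genes was 0.642 (permutation p = 0.0372, adjusted over 6 relations 0.0558), and 0.343 without high-fat 3 and 4. Since Alb parts the libraries into 3 high and 8 low, which a pooled correlation does not suit, a count was chosen after that result: 12 of the 20 genes had higher counts in each of the 3 libraries than in any other, where chance gives 0.121, among them Serpina1 (27, 116 and 44 counts), Ahsg (23, 73 and 37 counts) and Ambp (31, 55 and 39 counts). Of the 24 liver genes found, 6 passed the expression filter, so muscle or its other cells also hold some, and neither the route of such RNA nor a biological explanation was tested.

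Other animals that stood apart are given as values. Control animal 5 had Prx at 112 CPM (6.12 to 10.8 CPM in the other control animals), and 7 of the 9 measured nerve markers were highest in that library. Control animal 2 had the fast myosin gene Myh4 at 150 CPM (8.04 to 19.1 CPM in the other control animals) and Junb at 110 CPM (53.7 to 64.4 CPM). Control animal 3 had Irs1 at 39.2 CPM (14.1 to 20.6 CPM). High-fat animal 1 had P4ha1 at 42.9 CPM (34.7 to 36.8 CPM), Trim35 at 210 CPM (264 to 282 CPM) and a cytosolic ribosome score of 0.27 (-0.08 to 0.00). High-fat animal 2 had Timp1 at 11.2 CPM (32.1 to 49.1 CPM).

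Chance could not be excluded for the 523 genes at an unadjusted p under 0.05 or the 10 lists called. Of 100 splits, the real one included, 38 gave at least the 523 genes at an unadjusted p under 0.05, and 63 gave at least the 10 lists called with the preset correlation. The highest of the other splits gave 2045 genes and 24 lists. For the 0 genes called by edgeR's quasi-likelihood test (DESeq2 7, the likelihood ratio and exact tests 8 each, voom 0) the splits decide nothing, since all 100 reach a count of 0. The highest of the other splits called 54, and the same split had the highest absolute OXPHOS median, 0.37. Whether a structure of the samples or chance gave that split was not tested.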

How the results depend on the processing

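The pairs of left-out libraries, the composition covariate and the permutation test of list scores were chosen after the data were seen. Gene by gene, 0 were called by edgeR's quasi-likelihood test under each other scaling, filter and covariate, by its robust form, by voom, and without any 1 or either pair of libraries (300 to 827 at an unadjusted p under 0.05), while DESeq2 called 7, the likelihood ratio test 8 and the exact test 8. Of 1813 values of 70 named genes, 1772 kept their direction and side of the threshold, 23 passed it and 18 reversed. Tox2 fell below the filter in 5 of the 11 fits without 1 library and has no value there. Library-size scaling moved the median of all genes to 0.04.

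With all animals and the preset correlation, camera called 4 lists higher and 6 lower. With the name letter as covariate it called 3 higher and 9 lower, 12 in all. Of the 10, fast fibres (-0.37, adjusted p = 0.130) and matrix genes (0.28, adjusted p = 0.0892) were lost, and complexes III, IV and V and slow fibres were new. The fast fibre list was also lost with RLE (-0.47, adjusted p = 0.0562) and upper quartile scaling (-0.48, adjusted p = 0.0637), and nerve markers were new without a filter (-0.41, adjusted p = 0.0429). The 10 list calls became 0 with an estimated correlation, 0 with fry and 0 with the permutation test. They became 4 with the composition covariate (2 of them among the 10, inflammatory signalling and satellite cell genes). Without high-fat 4 and 5 there were 6 (1 of them among the 10, satellite cell genes), and without 1 library 4 to 16. With the composition covariate endothelium and heat shock genes were new (adjusted p = 0.0464 for each), and the loss of macrophage and matrix genes was built in, since their scores form part of it. The OXPHOS median (linear fit, all 11 libraries -0.11) was -0.11 and not called in the first 3 of these, -0.012 with the covariate, 0.019 without high-fat 4 and 5, and -0.19 to -0.0095 without 1 library. Without high-fat 4 and 5, complex I was 0.014, macrophage markers -0.044, matrix genes -0.069, Pf4 -0.038, Itgam -0.035, Cd14 -0.094 and Irs1 0.014. Without control 5 and high-fat 4, Irs1 was 0.025 and Prx 0.22. With the name letter as covariate Adipoq was 0.38. Without 1 library, Irs1 ranged from -0.24 to 0.21, Myh7 from -0.10 to 0.036, Adipoq from -0.72 to 0.23, Prx from -1.58 to 0.19 and Pf4 from -0.00412 to 0.56.

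No animal measure passed after adjustment under any alternative. For insulin, glucose and HOMA-IR, and for every measure without 1 animal, the splits were too few for a single measure to pass alone. The adjustment over 13 measures therefore decides little there. The insulin difference ran from 0.528 to 0.890 ng/ml without 1 animal and did not turn. Group differences turned without 1 animal for body weight (-60.3 to 12.4 g), heart (-0.134 to 0.0179 g), liver (-3.51 to 0.198 g), brain (-0.0615 to 0.0557 g) and glucose (-0.21 to 1.65 mmol), and for brain with medians (-0.0634 g) and ranks (-0.733). The OXPHOS score's r with HOMA-IR was 0.165 without the 2 farthest animals, 0.181 in control animals only and -0.309 to 0.0461 without 1 animal. With insulin these were 0.156, 0.235 and -0.298 to 0.0824, and with glucose r was 0.0216 in control animals only and -0.309 to 0.117 without 1 animal. Apart from the fewer libraries or animals, the cause of each change was not tested. With 5 and 6 animals, simulated changes were recovered in 34.3% of genes at 1.5-fold and in 65.7% at 2-fold. Differences of these sizes and smaller ones may therefore go uncalled. The simulation held 200 changed genes, and with fewer the adjusted threshold is stricter. In the real data Gadd45a, 2.94-fold higher, was not called by edgeR's quasi-likelihood test (adjusted p = 0.471).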

Other observations

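The relations and genes in this part were chosen after their values were seen, and no explanation was tested. Of the clock genes, Arntl, the activator of the core clock, ran from 3.20 to 58.6 CPM and Dbp, an output gene of the clock, from 39.4 to 349 CPM. They ran opposite to each other over the 11 libraries on the log2 scale (Pearson's r = -0.909, permutation p = 0.00012; Spearman's rho = -0.955, permutation p = 6e-05; adjusted over 6 relations, 0.00036 for both; r = -0.916 without the 2 libraries farthest from the median). The labels used here give no time of day for the tissue.

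The OXPHOS score followed the mitochondrial ribosome score (Pearson's r = 0.974, permutation p = 7e-05; Spearman's rho = 0.836, permutation p = 0.00231; adjusted over 6 relations, 0.00036 and 0.00462; r = 0.941 without the 2 farthest libraries). The relation of the fast fibre score to the OXPHOS score did not pass (r = 0.524, permutation p = 0.0975; rho = 0.518, permutation p = 0.108; adjusted, 0.117 and 0.113; r = 0.474 without the 2 farthest libraries). The first principal component held 26.9% of the variance and did not part the diet groups (permutation p = 0.39).

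The heat shock genes Hspa1a and Hspa1b, near-identical copies that short reads can hardly part, were at 1863 and 1990 CPM in high-fat animal 4 and at most 669 and 740 CPM in the other animals. Rpl30, a ribosomal protein gene with many pseudogenes, was 0.915 to 1.47 CPM in 4 libraries and 13.7 to 26.7 CPM in 7, with both diet groups in each set.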
